A study of Mus musculus with 6 samples.

How the data were processed

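Biotin-labelled RNA from sorted tumor cells of 6 tumors was hybridised to Affymetrix MTA 1.0 arrays, 1 array per tumor, 3 untreated and 3 treated with degarelix. The deposited value table holds log2 expression values. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, whose versions and settings are not given in the sources used here. RMA subtracts background, normalizes the arrays to a common distribution and summarises probes per transcript cluster, which compresses changes of dim genes and removes shifts shared by a whole array. The log2 scale was read from the deposited values, which lay between 1.96 and 13.7 with similar quartiles on all arrays. Array medians over transcript clusters were 4.70 to 4.84. The table had 72688 rows, of which 6732 were control or background probe sets and were left out of all tests. Its 23 background probe sets ranged from about 2.14 to 6.93, so no single limit of detection was set.

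Gene names came from the platform annotation supplied with the data. Of 65956 transcript clusters, 30604 had 1 gene symbol, 2146 had several and 33206 had none. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, which changed 1135 of them; no coordinates were taken from it. The unit tested was the brightest cluster of each of 30063 genes, with no filter on dim genes. Of 429 genes with more than 1 cluster, the clusters of 20 disagreed on the call and those of 0 were called in opposite directions. Of 587 list entries 529 were measured; the others were not analysed here. Near-identical paralogs may share signal, which was not tested, so members of such families are uncertain as single genes.

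Degarelix was compared with untreated in limma 3.58.1 (R 4.3.3) with lmFit and eBayes at default settings, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Changes are degarelix minus untreated on the log2 scale, with the moderated SE. Fixed before the data were examined were 21 gene lists and 11 lists of cell type markers, each tested with camera (preset correlation 0.01) and adjusted within its family, beside camera with an estimated correlation and fry. The number of called members was also counted after adjustment over the list alone. Genes were named by a rule fixed at the same time. Myc, Cxcl15 and Cxcr2 were among genes fixed by name, with 1 more that had no value among the genes tested. Cxcl15 and Cxcr2 were fixed because the study is known for them, so their choice was not independent of its published result. The list of myeloid-attracting factors also holds Cxcl15. The rule further took the 12 largest rises and 12 largest falls among called genes without overlap of the groups. It passed over unnamed models, small RNAs, receptors of smell and immune receptor segments (0 among the rises and 4 among the falls). Up to 4 members per list were named by adjusted p, with members that moved against their list. Data were simulated for this comparison with 30063 genes, 200 of them changed. There limma found 99 of 100 genes changed by a log2 of 1 and 78 of 100 changed by 0.5. It called 13 of 29838 unchanged genes. In the same data camera called a shifted list of 25 genes and did not call an unshifted list. The simulated genes were drawn independently of each other, whereas the measured G2/M and mitosis list had an estimated correlation of 0.70. The simulation therefore cannot show how the preset camera test behaves on lists of correlated genes.

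The alternatives were median centring, cyclic loess, quantile normalization over the tested genes, an intensity trend with robust variances, array weights, a filter on dim genes, the mean of a gene's clusters, the replicate number as a block, leaving out each sample, all clusters, a test against a 1.2-fold change and an estimated correlation. The planned array weights, limma's default, stopped before convergence and gave degarelix replicate 2 a weight of 17.5; gene-by-gene weights were added after that result was seen, and both are reported. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.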

Results

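Gene expression was measured on Affymetrix MTA 1.0 whole-transcript arrays in tumor cells sorted from mouse MCRedAL prostate tumor allografts. MCRedAL is a mouse prostate cancer line that expresses the red fluorescent protein mCherry. Cells were sorted as mCherry positive and negative for the leukocyte marker CD45, the myeloid marker CD11b and the macrophage antigen that Adgre1 encodes. There were 3 untreated tumors, called castration sensitive by the submitters, and 3 tumors from mice given degarelix, an antagonist of the gonadotropin-releasing hormone receptor that withdraws androgen. Mice were randomized between the groups, degarelix was given at a tumor size of about 500 mm2 (unit as in the labels), and all RNA had an integrity number of at least 9. The labels call the samples biological replicates. The titles of the degarelix samples carry the tag 7dPC, which the labels do not explain, so the time of sampling was not taken from it and is not known here. The comparison asked which transcripts of the tumor cells differed after androgen withdrawal, with 3 arrays per group limiting the precision. Of 30063 genes tested, between 30.4% and 35.1% per array lay above the brightest background probe set.

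Tumor cells of the same group resembled each other more than tumor cells of the other group. Pearson correlations across genes were 0.9948 to 0.9979 between arrays of the same group and 0.9867 to 0.99 between arrays of different groups. The first principal component held 63.9% of the variance and placed the untreated samples at -27.4 to -21.8 and the degarelix samples at 20.5 to 32.4. The second held 15.7% and placed untreated replicate 1 at 24.9, apart from untreated replicates 2 (-9.5) and 3 (-11.2). Genes are not independent replicates, and no test was made of these values.

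The 12 largest rises and 12 largest falls were taken from the genes that passed the test without overlap of the groups. The largest measured rise was that of Dmbt1, a secreted scavenger receptor of mucosal epithelia, from 6.64 ± 0.37 to 11.62 ± 0.49 (log2, mean ± SD, n = 3 per group), a 31.6-fold difference against an untreated mean within the range of the background probe sets, which reached 6.93. Krt15, a keratin of basal epithelial cells, rose by 3.88 on the log2 scale (SE 0.17), Plekhs1 by 3.54 (SE 0.14), the methyltransferase gene Inmt by 3.34 (SE 0.48), and both Agt, which encodes angiotensinogen, and the lipocalin gene Obp2a by 3.16 (SE 0.23 and 0.16). The chemokine genes Cxcl15 and Cxcl17 rose by 3.0 and 2.63, the matrix metalloproteinase gene Mmp7 by 2.59, Vtn, which encodes vitronectin, by 2.53, the carboxypeptidase gene Cpm by 2.46 and the arginase gene Arg1 by 2.38. The largest measured falls were those of Spinkl, whose treated mean was 2.89, at -4.60 (SE 0.77), Angptl7 at -3.69 (SE 0.24) and Pip, a secretory protein gene, at -3.42 (SE 0.73). Next came Mki67, which encodes the proliferation antigen Ki-67, at -3.00, the lipocalin gene Lcn12 at -2.62, the cyclin gene Ccna2 at -2.55, Hapln1 at -2.54, the topoisomerase gene Top2a at -2.53, the mitotic kinase gene Pbk at -2.39, Zfp185 at -2.31, the condensin gene Ncaph at -2.25 and the chemokine gene Ccl28 at -2.23. The untreated mean of 5 of the 12 rises and the treated mean of 10 of the 12 falls lay below the brightest background probe set, so their sizes and ranks are less certain. Adjusted p for these 24 genes in limma ranged up to 0.0205, that of Pip. Passing the test and having no overlap between the 3 treated and 3 untreated values were conditions of the choice, so neither adds support. The values of Spinkl varied widely among untreated tumors (SD 1.95) and those of Pip among treated tumors (SD 1.58). With an intensity trend and robust variances in limma the adjusted p was 0.0528 for Spinkl and 0.0973 for Pip, and Pip also lost its call without untreated replicate 2, degarelix replicate 1 or degarelix replicate 2 (adjusted p = 0.0537, 0.0873 and 0.0674).

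In all, 3529 genes changed in limma at an adjusted p under 0.05, of which 1264 (35.8%) were higher and 2265 lower after degarelix. By at least 2-fold, 138 genes were higher and 269 lower. The groups did not overlap for 9386 genes (31.2%), against 10% by chance with 3 against 3. The split depended on the scaling: with each array centred on its own median, 629 genes (21.9%) were higher and 2249 lower, and with quantile normalization 1644 (44.9%) were higher. It also depended on weights for the arrays, which gave 8888 genes (57.4%) higher and 6596 lower with limma's default, stopped before convergence, and 50.9% higher gene by gene. The count of changed genes was 2125 without untreated replicate 2, 1972 without untreated replicate 3, 1597 without degarelix replicate 1 and 1836 without degarelix replicate 2. It rose to 4702 without untreated replicate 1 and to 3817 without degarelix replicate 3. A test against a 1.2-fold change left 241 genes higher and 508 lower.

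**Figure D1:**
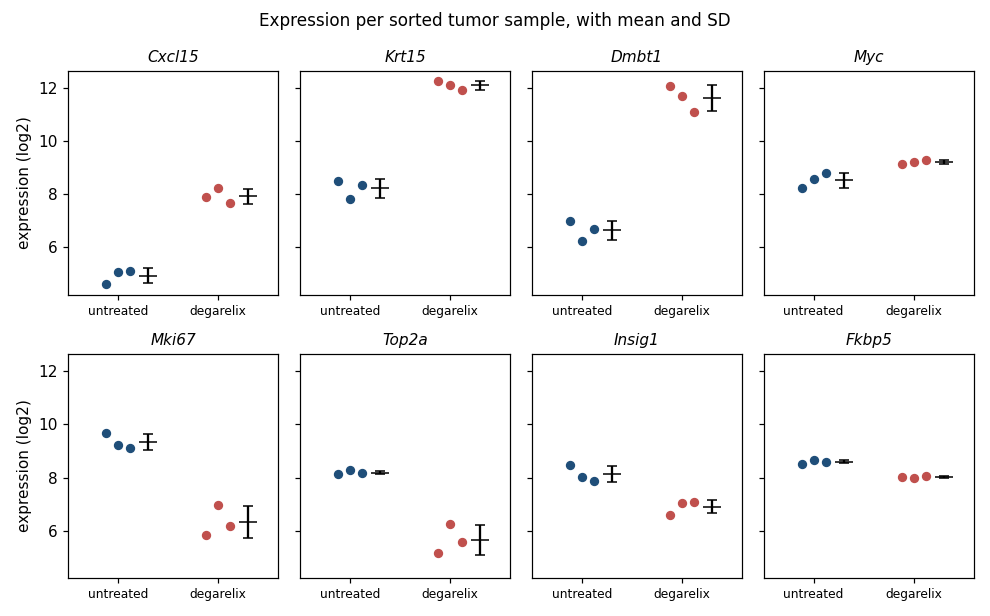
Expression (log2) of 8 genes in each sorted tumor sample, untreated in blue and degarelix in red, with the mean and SD of 3 samples in black; all panels share the vertical axis. Cxcl15, Krt15, Dmbt1 and Myc were higher and Mki67, Top2a, Insig1 and Fkbp5 lower in every degarelix sample than in any untreated sample.

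Cxcl15, a mouse chemokine that attracts neutrophils, rose from 4.93 ± 0.28 to 7.93 ± 0.29 (log2, mean ± SD, n = 3 per group), an 8.01-fold difference (limma adjusted p = 5.65e-05). Its level in untreated tumors lay within the range of the background probe sets. Cxcr2, a receptor for chemokines of this kind, was at 5.27 ± 0.05 and 5.23 ± 0.09. Its change of -0.04 (SE 0.07) did not pass the test (limma adjusted p = 0.752). Both of its levels also lay within the range of the background probe sets, so a change could have been missed. The mouse Myc gene rose by 0.68 (SE 0.13, limma adjusted p = 0.0135), a call that ended with median centring (adjusted p = 0.051). The oncogene that drives the parental Myc-CaP line is a human transgene, not the mouse gene that the array reads. Whether the probes also read that transgene was not tested.

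Genes of cell division fell together. All 26 measured members of the list of G2/M and mitosis genes were lower after degarelix, with a median change of -1.70. Besides Mki67, Ccna2 and Top2a, those that fell included the kinase gene Aurka at -1.20 (SE 0.07), the spindle motor gene Kif11 at -2.04 (SE 0.12), the checkpoint gene Bub1 at -1.56 (SE 0.09) and Anln, which acts in cytokinesis, at -2.15 (SE 0.14). Of 26 measured DNA replication and G1/S genes, 25 fell and none rose, with a median of -1.35. Rrm1 and Rrm2, the subunits of the enzyme that makes deoxyribonucleotides, changed by -1.99 and -2.03, the cyclin gene Ccne2 by -1.83 and the replication factor gene Cdc45 by -1.65. In each list 26 genes were lower when adjusted over the list alone. The camera test of each list against all other genes gave adjusted p = 3.11e-36 and 3.33e-30 with a preset correlation, and adjusted p = 0.159 for both with an estimated correlation. In fry, which tests whether the members move one way, the adjusted p was 0.00325 and 0.00354, and it was at most 0.0262 for the other lists that passed camera, apart from the stress response and antigen presentation lists below.

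Of 29 measured NF-kB targets, 15 rose and 2 fell, with a median change of 0.39. The adhesion molecule genes Icam1 and Vcam1 rose by 1.19 (SE 0.13) and 0.69 (SE 0.09), the neutrophil-attracting chemokine gene Cxcl5 by 0.97 (SE 0.11) and the prostaglandin synthase gene Ptgs2 by 0.92 (SE 0.12), while Cxcl10, an interferon-induced chemokine gene, and the superoxide dismutase gene Sod2 fell, at -0.62 and -0.36. The lowest value of this list, that of the cytokine gene Il1a, was -1.74 (adjusted p = 0.0871) and did not pass the test. Of 19 measured myeloid-attracting factors 6 rose and none fell (median 0.34). They included Cxcl15, Cxcl5 and the macrophage growth factor gene Csf1, which rose by 0.91 (SE 0.18). The lowest value, that of the cytokine gene Il1b, was -1.65 (adjusted p = 0.0926) and did not pass either; Il1a and Il1b were higher by 2.31 and 2.15 in untreated replicate 1 than in the other untreated samples. Of 18 immediate early and dissociation genes 6 rose and none fell (median 0.34), among them Dusp1 by 0.89, Jun by 0.65, Egr2 by 0.48 and Klf6 by 0.45; genes of this list also respond to the handling of tissue. Adjusted over the list alone, 18 NF-kB targets rose and 3 fell, 8 myeloid-attracting factors rose and 2 fell, and 10 immediate early genes rose. The preset camera test gave adjusted p = 1.22e-06, 0.0041 and 3.29e-05 for the 3 lists, and adjusted p = 0.0944, 0.227 and 0.229 with an estimated correlation. Calls lost without degarelix replicate 1 were those of Csf1 (adjusted p = 0.062), Cxcl10 (0.0532) and Sod2 (0.086); Sod2 also lost its call without untreated replicate 2 (0.0744), untreated replicate 3 (0.0822) or degarelix replicate 2 (0.0785), and Klf6 with median centring (0.0513).

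Of 16 measured cholesterol synthesis genes, 12 fell and 1 rose (median -0.47). Insig1, a sterol-regulated membrane protein gene, was lower at -1.23 (SE 0.17), the isomerase gene Idi1 at -0.92 (SE 0.09), Nsdhl at -0.85 (SE 0.11) and the demethylase gene Cyp51 at -0.71 (SE 0.08). The mevalonate kinase gene Mvk rose by 0.28 (adjusted p = 0.0445), a call that was lost on leaving out any of the 6 samples in turn (adjusted p = 0.0691 to 0.142). Of 15 fatty acid synthesis genes 4 fell (median -0.23), led by Acaca, the acetyl-CoA carboxylase gene, at -0.69 and the synthase gene Fasn at -0.50. Of 24 Myc targets and ribosome biogenesis genes 9 fell (median -0.34), among them Cad, a pyrimidine synthesis gene, at -0.97 and the transferrin receptor gene Tfrc at -0.88. Of 20 oxidative phosphorylation genes 7 fell (median -0.21), with Cycs, which encodes cytochrome c, at -0.58. None rose in these 3 lists. The counts adjusted over the list alone were 14 cholesterol genes lower and 1 higher, and 6 fatty acid, 15 ribosome and 11 oxidative phosphorylation genes lower. The preset camera test gave adjusted p = 1.76e-09 for cholesterol, 0.0104 for fatty acid, 2.94e-09 for ribosome and 4.58e-07 for oxidative phosphorylation genes, against adjusted p = 0.159, 0.184, 0.248 and 0.325 with an estimated correlation. The fatty acid call ended under cyclic loess (adjusted p = 0.0691). The size of these falls depended on the scaling: the median was -0.09 under cyclic loess and -0.12 under quantile normalization for oxidative phosphorylation genes, -0.20 and -0.24 for ribosome genes and -0.14 and -0.15 for fatty acid genes, and the 7516 brightest genes had a median change of -0.10.

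Hypoxia and glycolysis genes moved both ways, with 9 of 20 lower and 3 higher (median -0.30). The oxidoreductase gene Ero1a and the mitochondrial protein gene Bnip3 fell, at -1.88 (SE 0.07) and -1.03 (SE 0.10), while the hexokinase gene Hk2 and the glucose transporter gene Slc2a1 rose by 0.61 and 0.67. Of 20 genes of the unfolded protein and integrated stress response 5 rose and none fell (median 0.20), including the chaperone cofactor gene Dnajb9 at 0.74 and the disulfide isomerase gene Pdia6 at 0.42. Hypoxia genes adjusted over the list alone numbered 12 lower and 3 higher, and likewise 9 stress response genes rose and 1 fell. The preset camera test gave adjusted p = 1.39e-04 and 8.90e-04, and adjusted p = 0.229 and 0.326 with an estimated correlation. The stress response list did not pass fry (adjusted p = 0.0563). The stress response call was lost without degarelix replicate 3 (adjusted p = 0.0667) and with default array weights (0.104).

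Genes of the androgen response moved both ways, with 28 values above 0 and 7 below. Of 35 measured members, 9 were higher, 3 lower and 23 not past the test, with a median of 0.13. Fkbp5, a chaperone gene induced by androgens and glucocorticoids, fell by 0.57 (SE 0.07), and the kinase genes Camkk2 and Stk39 fell, at -0.40 and -0.37. The metalloreductase gene Steap4 rose by 1.37 (SE 0.10), Pdlim5 by 0.76 (SE 0.08) and Iqgap2 by 0.71 (SE 0.09). There were 13 members higher and 4 lower when adjusted over the list alone. The preset camera test placed the list above other genes (adjusted p = 0.00327), against adjusted p = 0.221 with an estimated correlation. In fry the adjusted p was 0.00478, with the members moving up. Stk39 lost its call without untreated replicate 3 (adjusted p = 0.057) or degarelix replicate 1 (0.0595).

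Few of the measured lineage genes passed the test. Of 12 basal epithelium genes 2 rose, Krt15 and Krt14 (by 0.38), and none fell (median 0.07). Of 14 luminal epithelium genes 2 rose, Krt19 by 1.88 (SE 0.12) and Ly6d by 1.05 (SE 0.15), and the tight junction gene Cldn3 fell by 0.31 (median 0.15). Of 16 mouse prostate secretory genes, Apof rose by 0.84 and Timp4 by 0.57, and the secretory protein gene Msmb fell by 0.50 (median 0.12). None of 16 neuroendocrine genes passed the test in limma. Chga, which encodes chromogranin A, and Eno2 had changes of 0.21 and 0.16 (adjusted p = 0.246 and 0.285). The median level was 4.21 in untreated and 4.36 in degarelix samples for secretory genes, and 5.39 and 5.47 for neuroendocrine genes. These levels lay within the range of the background probe sets, which reached 6.93. A fall of such dim genes could hardly have been seen, and small changes could have been missed. Of 18 epithelial-mesenchymal transition genes 5 rose and 2 fell (median 0.19), with the matrix metalloproteinase genes Mmp2 and Mmp14 at 1.62 and 0.96, the adhesion receptor gene Cd44 at 0.85 and Tgfb2 at -0.54. Mmp2 and Mmp14 were highest in degarelix replicate 3 (9.78 and 9.48), as was the fibroblast gene Dcn (9.43), and Dcn and Fbln1, another fibroblast gene, rose by 1.46 and 1.07 in the same samples. Adjusted over the list alone, 4 basal genes rose, 2 luminal and 2 secretory genes rose and 1 of each fell, 6 transition genes rose and 2 fell, and 0 neuroendocrine genes changed. The preset camera test gave adjusted p = 0.035 for basal, 0.0388 for luminal, 0.0346 for secretory and 0.0274 for transition genes, each with adjusted p = 0.326 with an estimated correlation, and 0.0662 for neuroendocrine genes. These calls were lost on leaving out single samples: without degarelix replicate 3 the adjusted p was 0.0539 for basal, 0.103 for luminal and 0.158 for transition genes, without untreated replicate 1 it was 0.18 for luminal genes, without untreated replicate 3 it was 0.0574 for basal and 0.0531 for secretory genes, and without degarelix replicate 1 it was 0.0547 for secretory genes. Krt14, Cldn3, Msmb and Tgfb2 each lost their call on leaving out degarelix replicate 1 (adjusted p = 0.0791, 0.128, 0.0894 and 0.0548) or degarelix replicate 2 (0.0803, 0.0982, 0.0582 and 0.0502), Krt14, Cldn3 and Msmb without untreated replicate 2 (0.0717, 0.137 and 0.0793), Krt14 and Cldn3 without untreated replicate 3 (0.05 and 0.136), and Cldn3 without degarelix replicate 3 (0.0666).

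Of 16 antigen presentation genes 3 rose and none fell (median 0.15), led by Tapbp, which encodes tapasin, at 0.43 (SE 0.07) and the immunoproteasome gene Psmb10 at 0.60 (SE 0.10). Of 25 interferon-stimulated genes 3 rose and 5 fell (median -0.05). The guanylate-binding protein gene Gbp2 rose by 1.18 (SE 0.16), while Rsad2, which encodes the antiviral protein viperin, and the RNA sensor gene Ifih1 fell, at -1.26 (SE 0.13) and -1.02 (SE 0.18). Of 16 glucocorticoid-responsive genes 2 rose and 3 fell (median 0.05), with the transcription factor gene Cebpd at 1.15 and Tsc22d3 at -0.60. Of 18 p53 targets 4 rose and 1 fell (median 0.02), with Trp53inp1 at 0.97 and the apoptosis gene Pmaip1 at -0.66. Adjusted over the list alone, 3 antigen presentation genes rose, 4 interferon-stimulated genes rose and 7 fell, 6 glucocorticoid-responsive genes rose and 4 fell, and 4 p53 targets rose and 2 fell. The preset camera test gave adjusted p = 0.00919 for antigen presentation (adjusted p = 0.326 with an estimated correlation, and 0.0548 in fry), 0.344 for interferon-stimulated, 0.583 for glucocorticoid-responsive and 0.604 for p53 genes. Without untreated replicate 1 the interferon-stimulated list was lower (adjusted p = 0.019).

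**Figure D2:**
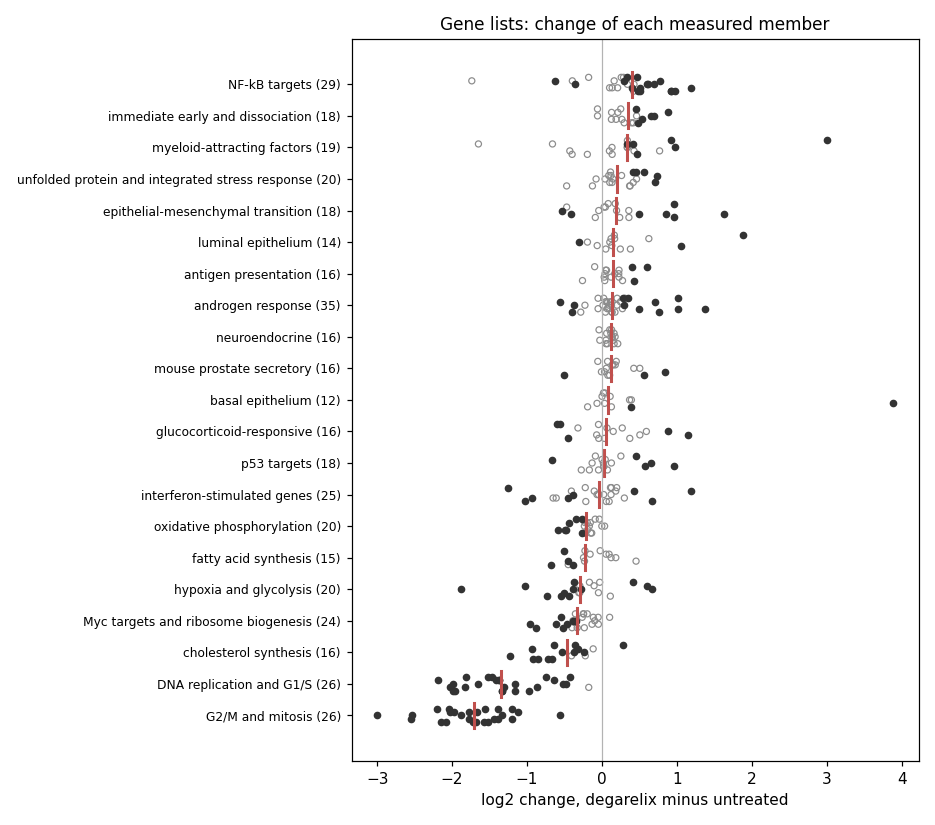
Change of each measured member of the 21 gene lists (log2, degarelix minus untreated), with filled points for genes past an adjusted p of 0.05 over all genes, open points for the others, a red bar at the median and the number of measured members in parentheses. The G2/M and DNA replication lists lie lowest, with medians of -1.70 and -1.35, and the NF-kB targets highest, with a median of 0.39.

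Markers of other cell types were read in the same samples because a sort can retain other cells. No list of the 11 passed the preset camera test in limma. The 17 macrophage and monocyte genes had a median change of -0.42 (adjusted p = 0.0578), with 15 values below 0 and only Ly6c2, a monocyte surface antigen gene, past the test, at 1.57 (SE 0.12). Lyz2, the macrophage lysozyme gene, was at 9.02, 6.26 and 7.65 in untreated replicates 1, 2 and 3 and at 5.51 to 6.27 after degarelix (change -1.72, SE 0.57, adjusted p = 0.0911). Without untreated replicate 1 the median of this list was -0.13 (adjusted p = 0.488), and without untreated replicate 2 it was -0.67 (adjusted p = 1.40e-07). Of 13 fibroblast genes, Dcn, which encodes decorin, rose by 1.46 (SE 0.29) and Fbln1, which encodes fibulin 1, by 1.07 (SE 0.11), with a median of 0.15 (list adjusted p = 0.078; 0.00158 without degarelix replicate 2 and 0.0313 without untreated replicate 3). Vwf fell by 0.71 among 11 endothelial genes (list adjusted p = 0.177; 0.00684 without untreated replicate 2). Rgs5 fell by 0.73 among 9 pericyte and smooth muscle genes (list adjusted p = 0.484), and Fabp4 and Pnpla2 fell, at -1.12 and -0.40, among 7 adipocyte genes (list adjusted p = 0.857; Pnpla2 adjusted p = 0.0529 without degarelix replicate 2). Ltf and Ly6g rose by 0.48 and 0.38 among 12 neutrophil genes (list adjusted p = 0.496); Ly6g lost its call on leaving out any sample but degarelix replicate 3 (adjusted p = 0.0839 to 0.168). Among 8 skeletal muscle genes Acta1 rose by 0.33 and Tnni2 fell by 0.59 (list adjusted p = 0.711), and both of these calls were lost on leaving out any sample but untreated replicate 1 (adjusted p = 0.0528 to 0.114 for Acta1 and 0.0784 to 0.114 for Tnni2). None of the 10 pan-leukocyte, 9 T cell, 8 NK cell or 6 B cell genes passed the test (list adjusted p = 0.484 for each); the pan-leukocyte list had adjusted p = 0.0332 without untreated replicate 2, and Cd52, Cd5, Gzmb and Cd79a had changes of -0.22, -0.21, 0.16 and 0.18. Adjusted over the list alone, 1 macrophage gene rose, 4 fibroblast genes rose and 1 fell, 2 neutrophil genes rose and 1 fell, 1 endothelial, 1 pericyte and 2 adipocyte genes fell, 1 skeletal muscle gene rose and 1 fell, and 0 genes of the other lists changed. The adipocyte median (0.14) and mean (-0.10) differed in sign, as did those of the skeletal muscle list (0.08 and -0.01).

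**Figure D3:**
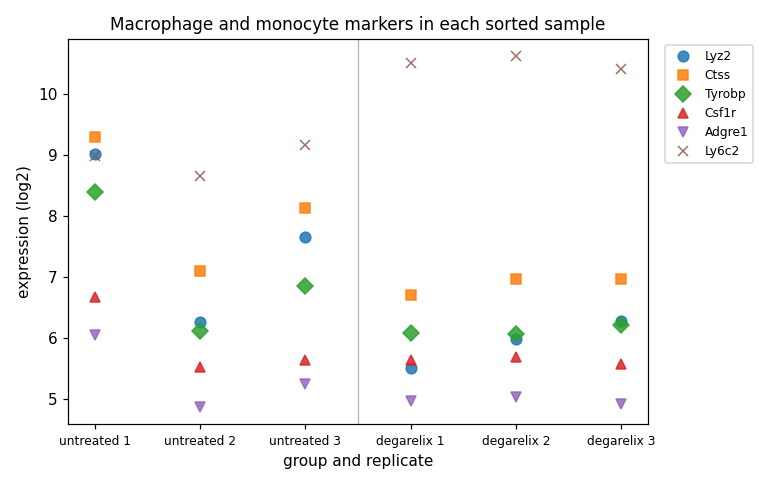
Expression (log2) of 6 macrophage and monocyte markers in each of the 6 sorted samples, with a symbol per gene and a line between the groups. Lyz2, Ctss, Tyrobp, Csf1r and Adgre1 were highest in untreated replicate 1, with Lyz2 at 9.02 there, and Ly6c2 was higher in all 3 degarelix samples.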

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

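All the tests in this part were chosen after the results were seen, and for small nuclear RNA genes the value that decides on brightness was changed from a count of calls to a median after the count was seen, and small nucleolar RNA genes with an approved symbol were split off last; the test of a shift of the whole array was changed from lymphoid lists, which lie near background, to genes of like brightness after both were seen. Transcript clusters outside the gene comparison also carried signal. Of 33206 clusters with no gene symbol, 336 were higher and 372 lower after degarelix in limma, adjusted over all 65956 clusters. Of 2146 clusters with several symbols, 41 were higher and 95 lower.

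Macrophage genes were higher in untreated replicate 1 than in the other untreated samples, although the sort excluded cells with CD45, CD11b or the macrophage antigen that Adgre1 encodes. The list medians were 6.83, 5.89 and 6.40 in untreated replicates 1, 2 and 3. After degarelix they were 5.94, 5.98 and 5.93, so untreated replicate 3 also lay above every degarelix sample. All 17 macrophage and monocyte genes in untreated replicate 1 lay above the mean of untreated replicates 2 and 3, by a median of 0.837 on the log2 scale. Of 10000 random lists matched on expression, 0 reached that median. Those lists drew genes one by one, whereas the macrophage list had an estimated correlation of 0.87, so this count does not measure chance. Ptprc, Adgre1, Itgam and Csf1r, which encode those antigens and the macrophage growth factor receptor, were higher by 0.66, 0.99, 0.76 and 1.09. A shift of the whole array would raise genes of like brightness alike. The 99th percentile of the random lists was 0.123, and the median over all genes was -0.0012. RMA removes shifts shared by a whole array, so both values are held near 0 and cannot decide on such a shift. They show only that genes of like brightness did not share the rise in the normalized values. Macrophage RNA in untreated replicate 1 is a candidate explanation that the macrophage values fit, at levels of 9.02 for Lyz2, 9.29 for Ctss and 8.39 for Tyrobp there, while 5 of the 17 genes were above the brightest background probe set in the other untreated samples as well. Whether such cells entered the gate or the tumor cells expressed these genes stays open, and no biological explanation was tested because the labels do not separate this sample from its group.

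Small nuclear RNA genes were lower after degarelix, 224 of 914 against 2 higher, with a median change of -0.59 for the 259 at a mean of at least 6; the class has many near-identical genomic copies, so these are not independent genes. Of 174 small nucleolar RNA genes of that level 15 were lower and 4 higher (median 0.0246), and of 151 microRNA genes 2 were lower and 5 higher (median 0.134, lower quartile 0.01), which goes against a lower recovery of all small RNA after degarelix. Such a loss stays open in part, since 136 of the small nucleolar RNA genes are predicted, the 38 with an approved symbol had a median of -0.20 with 9 lower against 2 higher, their lower quartile (-0.50) reaching below the upper quartile of the small nuclear RNA genes (-0.37), 5 of 18 Snora genes at any level were lower and none higher, and whether microRNA probes read host transcripts was not tested. A brightness-dependent shift is argued against by a median of -0.568 after cyclic loess (upper quartile -0.38), with 132 of the 224 calls still made, and by protein-coding genes of like brightness, the lowest of whose medians in 1000 draws was -0.0809. Signal shared between copies was not tested, and an effect of degarelix stays open as a hypothesis.

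The fall of cell cycle genes, 51 of 52 measured, was weighed against both dilution and scaling. Dilution by other cells would lower tumor cell genes alike. But 8 luminal genes with an untreated mean above the brightest background probe set had a median change of 0.183 (lower quartile -0.10). That of the cell cycle genes was -1.53. A brightness-dependent shift would be removed by cyclic loess, after which 51 cell cycle genes were still lower, with a median of -1.51. An effect of degarelix on proliferation remains, as a hypothesis found and tested on the same data. The 10 splits of the 6 samples are too few for a share under 0.05; the real split (1 of 10) gave 3529 genes and the highest of the others 0.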

How the results depend on the processing

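The alternatives of all clusters and of a test against a 1.2-fold change were applied only to counts of genes, not to lists or named genes. No gene or list that had passed the test changed direction under any of the other alternatives. Of 17 lists that passed, 11 did so under each of those other than an estimated correlation. Of 123 named genes that passed, 95 did so wherever they were tested. The call was lost by 24 in some leave-one-out fit and by 19 in another setting. Of the named genes that had not passed, 15 gained a call. With an estimated correlation no list passed: the adjusted p was 0.0944 for NF-kB targets, 0.159 for cholesterol synthesis, G2/M and DNA replication, 0.184 for fatty acid synthesis, 0.221 for androgen response, 0.227 for myeloid factors, 0.229 for hypoxia and immediate early genes, 0.248 for ribosome biogenesis, 0.325 for oxidative phosphorylation and 0.326 for antigen presentation, basal, luminal, secretory, transition and stress response genes. The estimated correlation was -0.0076 for NF-kB targets and -0.022 for fatty acid synthesis, both below the preset 0.01. Correlated members therefore do not account for the loss of those calls. Failing this setting is not by itself a sign that the members of a list are correlated. Default array weights gave 15484 genes, 8888 higher and 6596 lower, but stopped before convergence; gene-by-gene weights, added after seeing the data, gave 9917, 5051 and 4866. Under default and gene-by-gene weights the adjusted p was 0.154 and 0.0964 for transition, 0.174 and 0.131 for luminal and 0.00942 and 0.0127 for neuroendocrine genes, and 0.104 under default weights for the stress response. Median centring left 629 genes higher, and a test against a 1.2-fold change left 749 (241 higher, 508 lower). Under cyclic loess the adjusted p was 0.0691 for fatty acid, 0.0899 for secretory, 0.0351 for fibroblast and 0.0486 for macrophage genes, and under quantile normalization 0.113 for secretory and 0.0327 for fibroblast and macrophage genes. It was 0.0399 for macrophage genes with an intensity trend and 0.0506 for fatty acid synthesis with the dim filter, at an unchanged median of -0.23. The dim filter raised the gap between mean correlations within and between groups from 0.00756 to 0.0187. Leaving out 1 sample gave 1597 to 4702 changed genes (629 to 1649 higher, 968 to 3255 lower), 110 to 156 genes higher and 241 to 302 lower by at least 2-fold, and an adjusted p of 0.017 to 0.0574 for basal, 0.00684 to 0.667 for endothelial, 0.00602 to 0.158 for transition, 0.00158 to 0.368 for fibroblast, 0.019 to 0.776 for interferon-stimulated, 0.0056 to 0.18 for luminal, 1.40e-07 to 0.488 for macrophage, 0.0232 to 0.0547 for secretory, 0.019 to 0.192 for neuroendocrine, 0.0332 to 0.754 for pan-leukocyte and 2.56e-05 to 0.0667 for stress response genes. The labels give same-numbered samples no shared animal or day. Their deviations from the group means correlated at 0.163, 0.04 and 0.196 for replicates 1, 2 and 3. Between the groups, the highest correlation for samples of different number was 0.0292, and 6 of 6 arrays correlated best with their own number. Deviations from a shared group mean depend on each other, so these 6 matches are not independent, and their rate by chance was not worked out. They are a weak hint from the data, and whether same-numbered samples share more than a number stays open. The replicate block gave 3809 genes and a camera adjusted p of 0.0252 for fibroblast, 0.0189 for macrophage and 0.0393 for neuroendocrine genes. With that block Acta1, Ly6g, Mvk and Tnni2 lost their calls (limma adjusted p = 0.0536, 0.0603, 0.0683 and 0.0635). The cause of these changes was not tested. Signal over background limits dim genes, since at most 35.1% of genes per array lay above the brightest background probe set.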

Other observations

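All tests and genes in this part were chosen after the values were seen. Of 49 measured keratin genes, 12 were higher after degarelix, none were lower and 37 did not pass the test, with at least 10 higher and 0 lower under each scaling. Besides Krt15 and Krt19, the keratins of stratified epithelia Krt4 and Krt13 rose by 1.65 (SE 0.08) and 1.01 (SE 0.06). Tissue kallikreins, secreted proteases of which many in the mouse are near-identical copies, moved the other way, with 9 of 24 lower and none higher and 6 or 7 lower under the other scalings. Klk1b24 and Klk1b21 fell by 2.15 (SE 0.33) and 2.12 (SE 0.36). Signal shared between the copies was not tested, so the single genes stay uncertain. Of 31 histone genes of the replication-dependent clusters 20 were lower and none higher, with H2ac15 at -1.88 and H2bc21 at -1.50; 21 or 22 were lower under the other scalings.

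Genes of motile cilia were examined because a few of them stood out in degarelix replicate 3, so the list is not independent of these data, although the genes first seen were left out of it. Of 33 measured, 8 rose and none fell (median 0.12), including Rfx2, a transcription factor gene of ciliated cells, by 0.84 (SE 0.09) and Tppp3 by 0.64 (SE 0.10), but 3 rose under median centring or cyclic loess and 5 under quantile normalization. Among the genes that rose, only Rfx2 had an untreated mean (7.12) above the brightest background probe set, which reached 6.93. The untreated mean of Tppp3 was 6.90 and those of the others were lower. The camera p, unadjusted for the search, was 5.13e-05 with a preset correlation and 0.0817 with an estimated correlation. The median of these genes in degarelix replicate 3 differed from that of the other 2 treated samples by -0.0015, but Rfx2, Tppp3, Rsph1 and Cfap126 were highest in degarelix replicate 3 at 8.15, 7.71, 6.40 and 6.30, against 7.90 and 7.80 in the other 2 for Rfx2.

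Immunoglobulin V segments were higher for 26 of 203 and lower for none, but for 9 under both median centring and cyclic loess and 14 under quantile normalization. Pseudogenes were lower for 497 of 4423 and higher for 23, with 412 to 472 lower and 8 to 43 higher under the other scalings.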
